A study of Mus musculus with 6 samples.

How the data were processed

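RNA from heart tissue of C57BL/6 mice (C57BL/6J in the treatment protocol) was measured in 6 libraries, 3 from control mice (CON) and 3 from mice given angiotensin II (AngII), a peptide hormone that raises blood pressure and is widely used to induce cardiac hypertrophy. Per the labels' protocols, an osmotic pump under the skin delivered angiotensin II at 1 µg/kg/min, or saline, for 4 weeks, and the age label reads 10 weeks. The labels describe Trizol extraction, selection of poly(A) RNA and Illumina sequencing from both ends of each fragment. The extraction text also speaks of adipose tissue, while every tissue label reads heart. Group and replicate number were taken from the sample titles, and the columns of the table were matched to samples by those names.

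The authors deposited a single table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file headers, with 55385 genes in rows and the 6 libraries in columns. HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 are named per the submitters' processing notes, together with the genome builds mm8 and GRCm39. Those notes, as given here, assign no role to any of these, so the build behind the values is not given in the sources used here. Zero was written as 0.0001 in the deposited FPKM table, and from 62.5% to 63.8% of the values in a library equalled that number. Read counts were not analysed here. Gene symbols were taken from the table, and gene IDs were matched to the GENCODE mouse annotation release M21 on GRCm38, where 55144 of the IDs (99.6%) were found. Biotypes, transcript length, GC content and all coordinates came from that annotation. Where several rows shared a symbol, the row of highest mean FPKM stood for it in the gene lists.

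Depth was recovered from the values, because FPKM multiplied by transcript length moves in steps of 1 fragment for genes with a single transcript. The step gave 15.7, 14.3 and 15.9 M fragments for CON replicates 1, 2 and 3, and 14.8, 22.4 and 21.7 M fragments for AngII replicates 1, 2 and 3. Between 37.1% and 43.5% of the low values in a library lay within 0.1 of a whole fragment, so the values are not whole read counts and no count model was applied. On simulated data the step was recovered to within 0.39%. At this depth the spread between replicates falls with the level of a gene. The median coefficient of variation between CON libraries was 13.2% for genes of 1 to 2 FPKM and 2.73% for genes of 100 to 5000 FPKM.

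Values were transformed to log2(FPKM + 0.5), and genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 10697 genes, of which 9415 were protein-coding. AngII was compared with CON by limma 3.58.1 in R 4.3.3, with a mean-variance trend, two-sided moderated tests and Benjamini-Hochberg adjustment over all genes kept. The threshold was an adjusted p of 0.05 with no limit on fold change. Every fold change is on the log2(FPKM + 0.5) scale and so understates the change of low genes. For Usp25 and Atp2a2, which the title of the series concerns, an exact two-sided permutation test was added, whose smallest possible p with 3 libraries against 3 is 0.1. The design text speaks of 3 mice in each group, but nothing given here ties each library to a mouse, so p-values measure the spread between these libraries, which may be technical.

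The following choices were made before the data were examined: the model, the threshold, the alternatives, the rule for named genes and 34 gene lists. The lists covered fetal and hypertrophy marker, adult sarcomere, calcium handling, potassium and sodium channel, collagen and extracellular matrix, TGF-beta pathway, cytokine, interferon-stimulated, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, renin-angiotensin, ubiquitin-specific protease, unfolded protein response and cell cycle genes. They also covered markers of fibroblasts, macrophages, lymphocytes, neutrophils and mast cells, endothelium, smooth muscle and pericytes, atrium, ventricle, red blood cells, adipocytes, skeletal muscle, mesothelium, and lung and thymus. Immediate early, circadian clock, mitochondrially encoded, cytosolic ribosomal protein and sex-linked genes completed them. Each list with at least 5 genes kept (27 lists) was tested against all other genes with camera in limma at a preset inter-gene correlation of 0.01, and again with a correlation estimated for that list. Adjustment was over the 27 lists. The directional test fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, was run beside it. Changed members were counted at the adjusted p over all genes and again adjusted over the list alone.

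Genes were named by rule. In each direction these were the 12 largest changes among genes past the threshold with a mean of at least 2 FPKM and no overlap between the 3 AngII and the 3 CON values. Added to them were Usp25, Atp2a2, each ubiquitin-specific protease gene past the threshold, up to 4 members past the threshold with the largest changes in each list (up to 2 of smallest p where none passed), and the textbook markers Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1, Col3a1, Postn, Ccn2, Tgfb1 and Pln.

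The pipeline was tested on simulated data for the AngII against CON comparison, with 10697 genes, a replicate spread of 3% beyond counting noise and 200 changed genes. It recovered 32% of genes changed by 1.25-fold, 64% of those changed by 1.5-fold, 92% at 2-fold and 98% at 4-fold, and called 7 of 10497 unchanged genes. Far fewer genes changed there than passed in the data. Because the adjustment depends on that share, these rates do not carry over directly to the real comparison. In the list test, the single list that had been shifted was the single list called. Alternatives covered pseudocounts of 0.1 and 1, no filter or a mean of at least 5 FPKM, median-of-ratios, trimmed-mean and quantile scaling, rescaling of each library to the same sum (TPM), the same without mitochondrial genes, other variance models and the replicate number as a block. Others were leaving out each library in turn, fold-change thresholds of 1.5 and 2, an unadjusted p, and other list tests. Removal of GC and length trends with splines of 5 degrees of freedom, and rescaling on nuclear protein-coding genes, were added after the data had been seen, as were the protease list without Usp6nl, which is no protease, and an estimated correlation for lists called in a setting other than the main one alone. Figures were drawn with matplotlib 3.10.9. No label gives a sequencing batch or date, so none could be examined.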

Results

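The series measured gene expression in the hearts of mice given angiotensin II for 4 weeks and in the hearts of control mice, with 3 libraries in each group. Its title concerns USP25, a ubiquitin-specific protease that removes ubiquitin from other proteins, and SERCA2a, the calcium pump of the cardiac sarcoplasmic reticulum encoded by Atp2a2. The single comparison in the design is AngII against CON. Depth, as recovered from the FPKM values, was 14.3 to 15.9 M fragments in CON and 14.8 to 22.4 M fragments in AngII. The deposited FPKM summed to 705654, 707038 and 710679 in CON replicates 1 to 3 and to 622479, 595803 and 606779 in AngII replicates 1 to 3. Mitochondrial genes held 43.5% to 44.8% of the FPKM in each library. The 7 pseudogenes above 1000 FPKM held 26.9% to 27.3% in CON and 20.9% to 22.2% in AngII. Among them, Gm28437 and Gm29216 are near copies of mitochondrial sequence. The similar share of mitochondrial genes alone therefore does not show that all mitochondrial sequence held an equal share in the 2 groups. On the log2(FPKM + 0.5) scale, Pearson's r across genes, which are not independent replicates, was 0.967 to 0.980 between libraries of a group and 0.897 to 0.904 between groups. The first principal component, which separated the groups, held 69.9% of the variance. No pair of libraries held an identical value above 1 FPKM for any gene.

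In AngII hearts, lists of sarcomere, calcium handling, tricarboxylic acid cycle and fatty acid oxidation genes were higher, and lists of interferon-stimulated, endothelial, immediate early and ribosomal protein genes were lower. With an estimated correlation the interferon-stimulated list kept its call (adjusted p = 0.0376), and the other 7 lost theirs (adjusted p = 0.0832, or 0.0959 for calcium handling). Skeletal alpha-actin (Acta1), an actin of the fetal heart that returns in hypertrophy, went from 75.4 ± 0.892 to 1313 ± 63.3 FPKM (mean ± SD, n = 3 in each group), a log2 fold change of 4.11. Both genes in the title of the series rose, Usp25 by 0.53 and Atp2a2 by 1.20 on the log2 scale. Adult sarcomere genes had a median of 0.94 and endothelial markers of -1.30 beside them. All 23 interferon-stimulated genes tested and all 16 endothelial markers tested fell. Of the 10697 genes tested, 6022 (56.3%) passed the limma threshold, 2983 higher and 3039 lower in AngII. At least a 2-fold change was reached by 701 of the higher genes and 809 of the lower ones. In 6005 of the 6022 genes the AngII and CON values did not overlap, against 6949 of all genes tested, where chance gives 10%. When each library was rescaled to the same sum (TPM), 6143 genes passed, 4029 higher and 2114 lower, with the median log2 fold change of all genes at 0.18 instead of -0.01. Without mitochondrial genes the split was 4017 higher and 2162 lower, with that median also at 0.18. That setting kept the 7 pseudogenes above 1000 FPKM, whose share differed between the groups, so it is no check independent of TPM. On nuclear protein-coding genes alone, rescaled, which leaves out both, the split was 2423 higher and 3159 lower, with a median of -0.08.

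**Figure D1:**
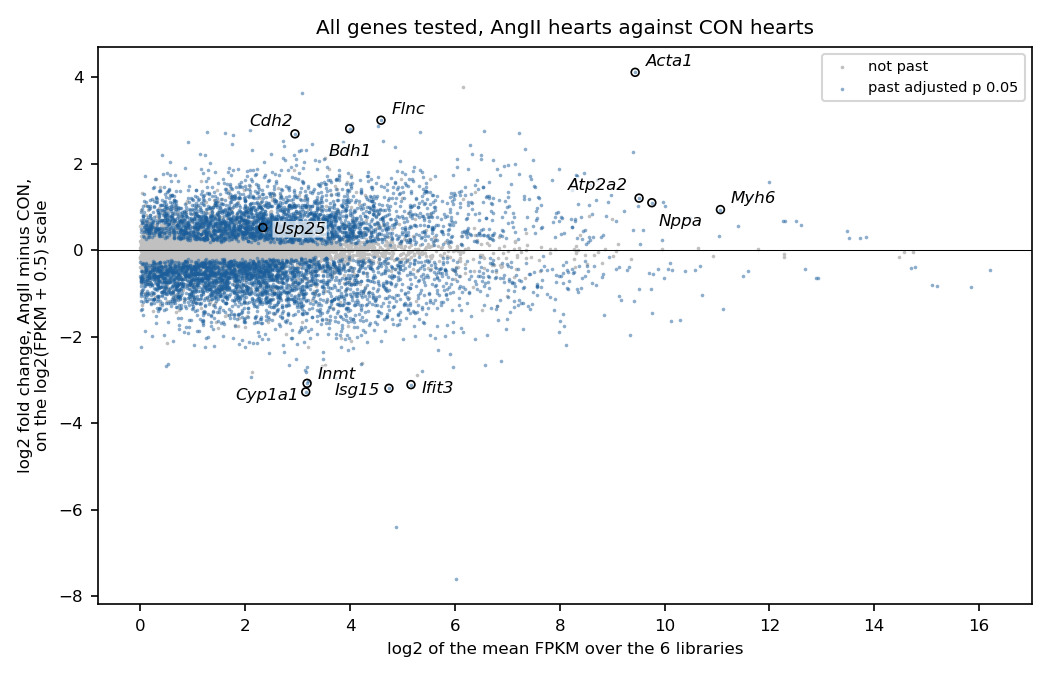
Log2 fold change (AngII minus CON, on the log2(FPKM + 0.5) scale) against the log2 mean FPKM over the 6 libraries for the 10697 genes tested, with the 6022 genes past an adjusted p of 0.05 in blue and 12 genes named. Acta1 lies highest of the named genes at 4.11 and Cyp1a1 lowest at -3.27.

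Usp25 (ENSMUSG00000022867; chromosome 16, 77013706 to 77116780 on the plus strand in GRCm38) was measured at 4.24, 3.81 and 4.11 FPKM in CON and 5.65, 6.44 and 6.09 FPKM in AngII. The means were 4.05 ± 0.218 and 6.06 ± 0.397 FPKM (SD, n = 3). The log2 fold change was 0.53 (SE 0.07, 95% confidence interval 0.35 to 0.70), with an adjusted p of 0.00139 in limma and 0.00181 when adjusted over the list alone. Atp2a2 (ENSMUSG00000029467; chromosome 5, 122453513 to 122502225 on the minus strand in GRCm38) was measured at 452.0, 437.4 and 437.4 FPKM in CON and 983.4, 1046 and 1031 FPKM in AngII. The means were 442.3 ± 8.40 and 1020.3 ± 32.8 FPKM (SD, n = 3). The log2 fold change was 1.20 (SE 0.04, 95% confidence interval 1.12 to 1.29), with a limma adjusted p of 5.12e-06. For both genes every AngII library lay above every CON library, and the exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. These are levels of mRNA, and the stability of the SERCA2a protein was not measured. Adult sarcomere genes had a median of 0.94 in the same comparison, calcium handling genes, which include Atp2a2, of 0.99 and endothelial markers of -1.30. Whether either rise goes beyond that of cardiomyocyte genes in general was not tested.

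**Figure D2:**
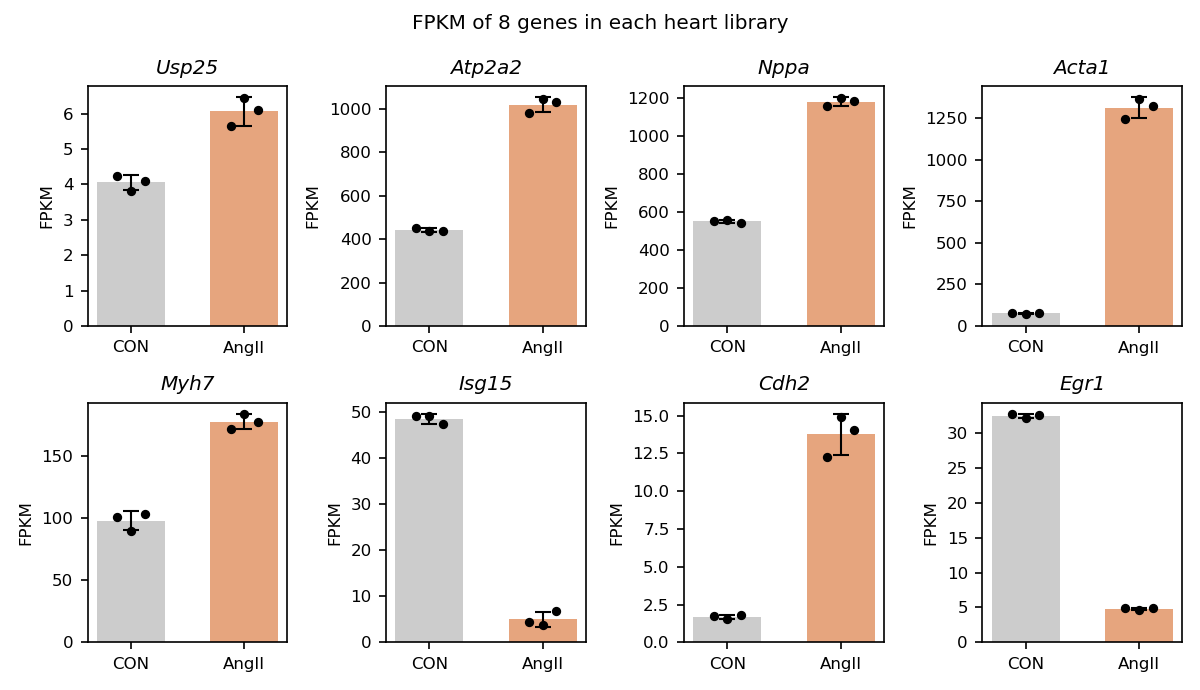
FPKM of 8 genes in each library (points), with the group mean (bar) and SD (error bar) of the 3 CON and 3 AngII libraries; each vertical axis starts at 0. Usp25, Atp2a2, Nppa, Acta1, Myh7 and Cdh2 were higher in every AngII library than in any CON library, and Isg15 and Egr1 were lower.

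The fixed list of ubiquitin-specific proteases had 36 genes tested, of which 13 rose and 6 fell, the same adjusted over the list alone, and it was not called (camera adjusted p = 0.131 in limma, and adjusted p = 0.181 with an estimated correlation). Endothelial markers (median -1.30) and smooth muscle and pericyte markers (-0.95) were lower in the same libraries. The list included Usp6nl, a Rab GTPase-activating protein and no protease. Without Usp6nl, left out after the results were seen, 13 of 35 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.0920 in limma, and adjusted p = 0.158 with an estimated correlation). Among genes with a mean of at least 5 FPKM, 9 proteases were tested, with a median of 0.53 instead of 0.20, and the list was called (adjusted p = 0.0245), a call lost with an estimated correlation (adjusted p = 0.146). The largest rises were in Usp28, a paralog of Usp25, from 8.64 ± 0.416 to 23.1 ± 0.734 FPKM (log2 fold change 1.37), and Usp13, from 9.61 ± 0.0345 to 20.8 ± 1.63 FPKM (1.07). Usp24 (0.80), Usp15 (0.79), Usp5 (0.75), Usp14 (0.70), Usp47 (0.61), Usp19 (0.50), Usp32 (0.40), Usp8 (0.31), Usp9x (0.31) and Usp38 (0.25) also rose, besides Usp25. The deepest fall was in Usp18, which removes the ubiquitin-like protein ISG15 and is itself interferon-stimulated, from 7.96 ± 0.788 to 1.42 ± 0.199 FPKM (-2.14). The proteases Usp42 (-0.56), Usp48 (-0.47), Usp12 (-0.31) and Usp36 (-0.22) fell as well, and so did Usp6nl (-0.61). Without any 1 library the call of Usp36 was lost, at a log2 fold change of -0.24 to -0.18 and adjusted p from 0.0614 to 0.113. Usp12 lost its call without any 1 library except CON replicate 1 (adjusted p up to 0.0798), Usp38 except AngII replicate 2 (up to 0.104), Usp8 except AngII replicate 1 (up to 0.0895) and Usp9x except AngII replicate 3 (up to 0.0805). Usp32 lost it without AngII replicate 1 (adjusted p = 0.0504) or 2 (adjusted p = 0.0575). Over all settings the call was lost in 14 for Usp36 (adjusted p up to 0.683), in 9 for Usp38, and in 8 each for Usp12 (up to 0.335), Usp8 and Usp9x (up to 0.423), none of which changed direction.

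Of 13 fetal and hypertrophy marker genes tested, 10 rose and none fell (11 and 0 adjusted over the list alone; camera adjusted p = 1.33e-06 in limma, and adjusted p = 0.0894 with an estimated correlation). The natriuretic peptide genes Nppa and Nppb, secreted by stretched cardiomyocytes, rose from 550.8 ± 7.51 to 1181 ± 22.1 FPKM (log2 fold change 1.10, adjusted p = 4.05e-06 in limma) and from 176.8 ± 8.88 to 301.6 ± 22.3 FPKM (0.77, adjusted p = 0.000214 in limma). Myh7, the slow beta-myosin heavy chain, rose from 98.1 ± 7.24 to 177.8 ± 5.99 FPKM (0.86). Myh6, the adult alpha-myosin heavy chain, rose as well, from 1469 ± 20.4 to 2821 ± 115 FPKM (0.94). Xirp2 (2.38), Cilp (2.04) and Mybpc2 (1.90) were the largest rises after Acta1. In the same libraries endothelial markers had a median of -1.30 and smooth muscle and pericyte markers of -0.95. Adult sarcomere genes had a median of 0.94, above the rises of Myh7 and Nppb. Myh7 also rose less than Myh6, so these values show no shift from Myh6 to Myh7.

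Among 19 adult sarcomere genes, 16 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 6.54e-07 in limma, and adjusted p = 0.0832 with an estimated correlation). Cardiac alpha-actin (Actc1) went from 2040 ± 21.5 to 6132 ± 156 FPKM (log2 fold change 1.59), alpha-actinin-2 (Actn2) from 198.3 ± 1.71 to 568.1 ± 17.9 FPKM (1.52), and the M-band gene Myom1 from 43.4 ± 1.85 to 124.0 ± 2.03 FPKM (1.51). Titin (Ttn) rose by 1.54, with CON replicate 2 at 4.56 FPKM against 10.2 FPKM in each of the other CON libraries, and with GC and length trends removed its log2 fold change was 0.57 (adjusted p = 0.108). Of 5 ventricular markers, 4 were higher and none lower, the same adjusted over the list alone (camera adjusted p = 0.010 in limma, and adjusted p = 0.0959 with an estimated correlation), including Fhl2 (1.63), Irx3 (1.01), Irx4 (1.00) and Myl3 (0.33). Under quantile normalization the list had an adjusted p of 0.0773, and Myl3 was at 0.18 (adjusted p = 0.246). Of 5 atrial markers tested, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.854 in limma), with Nppa at 1.10, Dkk3 at 0.44, Stard10 at -0.49 and Gja5 at -1.21. The atrial genes Myl4, Myl7, Sln and Bmp10 of that list lay below a mean of 1 FPKM and were not tested. Dkk3 lost its call without CON replicate 2 or 3 or AngII replicate 1 or 2, with adjusted p up to 0.0688. With no filter on low values its call was lost too (adjusted p = 0.0612). The sarcomere and ventricular rises stood beside a median change of -1.30 in endothelial markers and -0.95 in smooth muscle and pericyte markers.

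Calcium handling genes rose as a list, with 12 of 19 higher and 3 lower (14 and 3 adjusted over the list alone; camera adjusted p = 0.000335 in limma, and adjusted p = 0.0959 with an estimated correlation). Beside Atp2a2, the ryanodine receptor Ryr2, which releases calcium from the sarcoplasmic reticulum, rose from 6.26 ± 0.163 to 21.3 ± 0.186 FPKM (log2 fold change 1.69), the sodium-calcium exchanger Slc8a1 from 3.01 ± 0.0328 to 8.24 ± 0.220 FPKM (1.32) and Asph from 3.62 ± 0.0837 to 9.27 ± 0.634 FPKM (1.24). The calcium-binding protein gene Casq2 rose by 1.94, with CON replicate 2 at 21.6 FPKM against 75.5 and 72.1 FPKM. Phospholamban (Pln), the inhibitor of SERCA2a, rose from 141.1 ± 3.32 to 236.8 ± 3.71 FPKM (0.74, adjusted p = 1.59e-05 in limma). Of 18 cardiac potassium and sodium channel genes, 13 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.00226 in limma, and adjusted p = 0.0832 with an estimated correlation). The largest rises were Kcnj12 (1.67), the pacemaker channel gene Hcn2 (1.55), Kcnq1 (1.46) and Kcnj11 (1.40). Endothelial markers, at a median of -1.30, were lower in the same libraries.

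Most fuel oxidation genes rose, while genes of the respiratory chain went both ways and endothelial markers were lower (median -1.30). Of 18 tricarboxylic acid cycle genes, 16 rose and none fell (17 and 0 adjusted over the list alone; camera adjusted p = 1.55e-09 in limma, and adjusted p = 0.0832 with an estimated correlation), with a median log2 fold change of 1.38. Aconitase 2 (Aco2) went from 108.9 ± 1.64 to 398.8 ± 10.4 FPKM (1.87), Mdh1 rose by 1.75, Ogdh by 1.73 and Idh3a by 1.71. Mdh1 was at 76.8 FPKM in CON replicate 3 against 195.2 and 190.6 FPKM in the other CON libraries. Its change lay between 1.31 and 1.98 without any 1 library. Of 32 fatty acid oxidation genes, 26 rose and 3 fell (26 and 4 adjusted over the list alone; camera adjusted p = 8.67e-09 in limma, and adjusted p = 0.0832 with an estimated correlation). These included the electron transfer flavoprotein genes Etfa (1.87) and Etfdh (1.80), the acyl-CoA synthetase gene Acsl1 (1.84) and Pdk4 (1.75), whose product restrains glucose oxidation. Of 21 glycolysis genes, 16 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 5.78e-05 in limma, and adjusted p = 0.181 with an estimated correlation), with hexokinase 2 (Hk2) at 1.23, Pgk1 at 1.20, Pfkm at 1.17 and Pfkp at 1.05. Of 71 nuclear-encoded oxidative phosphorylation genes, 31 rose and 21 fell (33 and 21 adjusted over the list alone), and the list was not called (camera adjusted p = 0.112 in limma, and adjusted p = 0.715 with an estimated correlation). Uqcrc2 (1.64), Ndufs1 (1.55), Sdha (1.25) and Sdhd (1.20) were its largest changes. The list passed when libraries were rescaled to TPM (adjusted p = 0.0277), without mitochondrial genes (0.0268), with no filter on low values (0.0155) and with GC and length trends removed (0.00297). Each of these 4 calls was lost with an estimated correlation (adjusted p = 0.670, 0.628, 0.615 and 0.269). On nuclear protein-coding genes alone, rescaled, the list was not called. Among the 13 mitochondrially encoded genes, 6 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.815 in limma). Their median was -0.03 and their mean 0.00379, and camera pointed up. Among them mt-Nd4l (0.67) and mt-Nd5 (0.58) rose and mt-Co3 (-0.83) and mt-Nd3 (-0.64) fell, values that are uncertain because near-identical nuclear pseudogenes such as Gm28437 (44411 FPKM in CON) share their reads. Under quantile normalization mt-Co3 was at -0.02 (adjusted p = 0.374), so its fall was not seen there.

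**Figure D3:**
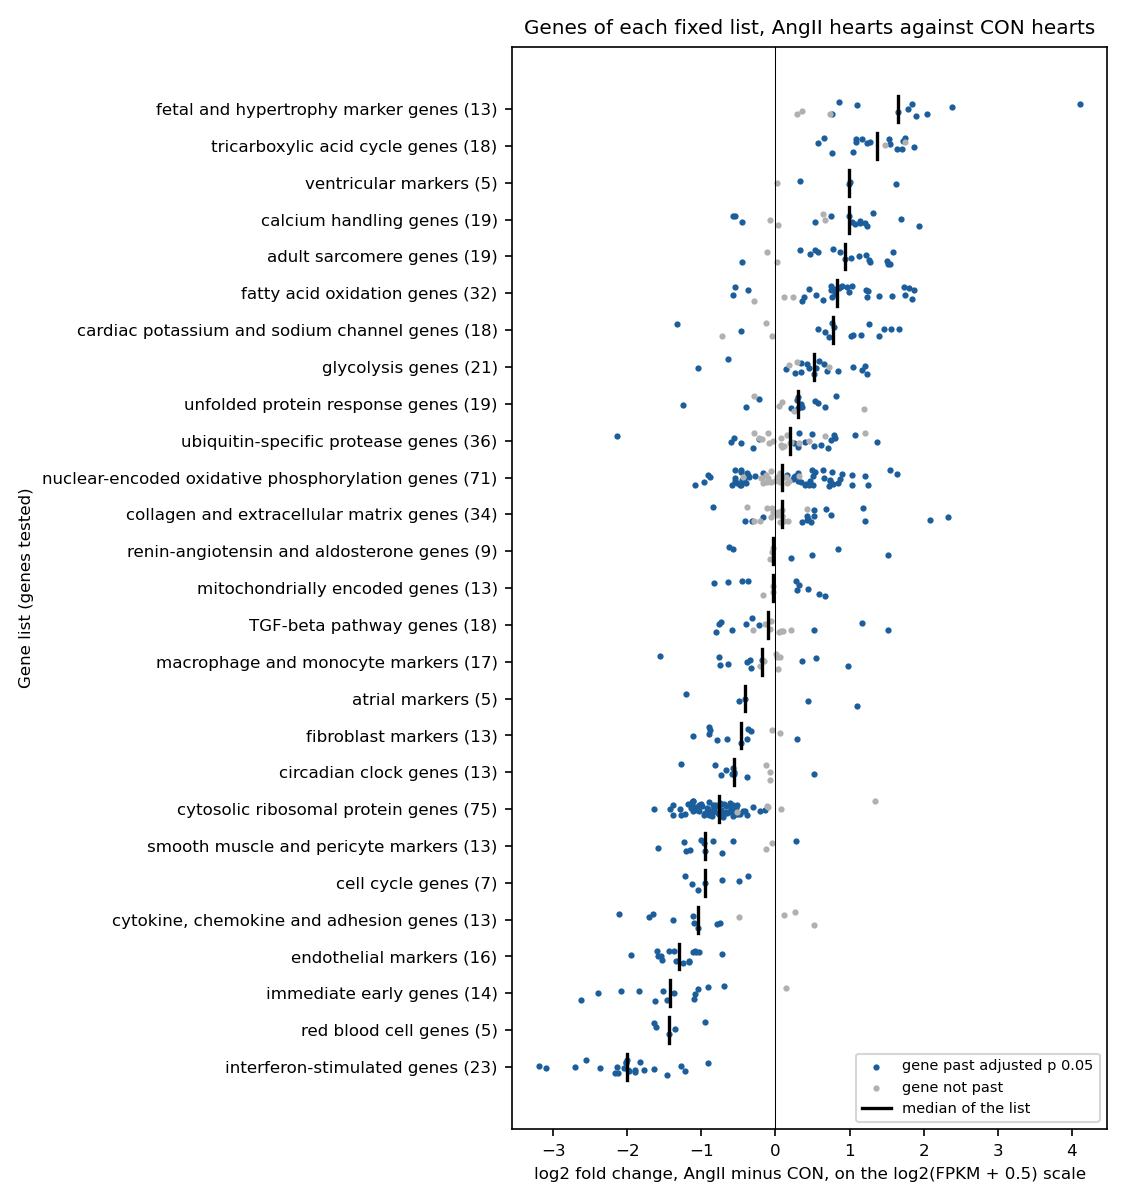
Log2 fold change (AngII minus CON, on the log2(FPKM + 0.5) scale) of each gene in the 27 lists tested, sorted by the list's median (black bar), with genes past an adjusted p of 0.05 in blue and others in grey. Medians ran from -2.01 for interferon-stimulated genes to 1.66 for fetal and hypertrophy marker genes.

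Matrix genes changed in part, beside a median of -0.47 in fibroblast markers. Of 34 collagen and extracellular matrix genes, 13 rose and 4 fell, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.0646 in limma, and adjusted p = 0.181 with an estimated correlation). Thbs4 rose from 1.13 ± 0.203 to 7.62 ± 0.200 FPKM (log2 fold change 2.33), the metalloproteinase inhibitor gene Timp1 from 3.54 ± 0.729 to 16.6 ± 1.77 FPKM (2.09), periostin (Postn) from 3.65 ± 0.369 to 9.09 ± 0.138 FPKM (1.21) and Col8a1 from 1.84 ± 0.0562 to 4.79 ± 0.0572 FPKM (1.18). Col1a1, the main fibrillar collagen chain, rose by 0.43 and Ccn2 by 0.42. Col3a1 was at 20.97 ± 1.14 FPKM in CON and 22.7 ± 0.495 FPKM in AngII (adjusted p = 0.132 in limma). Both the list (adjusted p = 0.00783) and Col3a1 (adjusted p = 0.00575) passed in limma when libraries were rescaled to TPM, and also without mitochondrial genes (0.00786 and 0.00464). With an estimated correlation the list lost these calls (adjusted p = 0.331 and 0.213). The setting without mitochondrial genes kept the 7 pseudogenes above 1000 FPKM. On nuclear protein-coding genes alone, rescaled, neither the list nor Col3a1 passed. The list passed with no filter on low values (0.00465) and with GC and length trends removed (0.0479) too, but not with an estimated correlation (adjusted p = 0.0546 and 0.115). Of 18 TGF-beta pathway genes, 3 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.365 in limma), with a median between -0.31 and 0.08 over the settings tried. Serpine1 (1.52) and Ltbp2 (1.17) rose, while Ltbp4 (-0.80) and Tgfb1, the gene of the ligand itself (-0.77, 9.53 ± 0.0793 to 5.38 ± 0.106 FPKM), fell. Of 9 renin-angiotensin and aldosterone genes, 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.578 in limma). Their median was -0.03, between -0.12 and 0.15 over the settings, while their mean was 0.19 and camera pointed up. Angiotensinogen (Agt) rose from 1.46 ± 0.306 to 5.10 ± 0.196 FPKM (1.52) and Lnpep by 0.85, and the peptidase genes Anpep (-0.63) and Enpep (-0.58) fell.

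The interferon-stimulated list was the single list that held its call with an estimated correlation. All 23 of its genes tested fell, also when adjusted over the list alone (camera adjusted p = 1.26e-11 in limma, and adjusted p = 0.0376 with an estimated correlation), with a median log2 fold change of -2.01. Macrophage markers had a median of -0.18 and endothelial markers of -1.30 in the same comparison. Isg15, a ubiquitin-like modifier, went from 48.5 ± 1.05 to 5.03 ± 1.66 FPKM (-3.19), Ifit3 from 64.6 ± 2.86 to 7.07 ± 0.346 FPKM (-3.10), Bst2 from 108.9 ± 4.62 to 16.3 ± 1.59 FPKM (-2.71) and Ifi27l2a from 201.4 ± 3.25 to 33.9 ± 4.53 FPKM (-2.56). Of 13 cytokine, chemokine and adhesion genes, 9 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.00504 in limma, and adjusted p = 0.0832 with an estimated correlation), led by the interferon-induced chemokine gene Cxcl9 (-2.12), Cxcl12 (-1.71), Ccl11 (-1.66) and Ccl7 (-1.39).

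Markers of most cell types other than cardiomyocytes were lower. All 16 endothelial markers fell, also when adjusted over the list alone (camera adjusted p = 1.55e-09 in limma, and adjusted p = 0.0832 with an estimated correlation), among them the apelin receptor gene Aplnr (-1.95), Tie1 (-1.61), Emcn (-1.59) and Egfl7 (-1.54). Of 13 smooth muscle and pericyte markers, 10 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.000299 in limma, and adjusted p = 0.0959 with an estimated correlation), with Tagln at -1.58, Lmod1 at -1.24, Myh11 at -1.21 and Kcnj8 at -1.16. Of 13 fibroblast markers, 10 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00401 in limma, and adjusted p = 0.0832 with an estimated correlation), including Dpt (-1.11), Scara5 (-0.90), Vim (-0.90) and Thy1 (-0.88). Macrophage and monocyte markers went both ways, 3 of 17 higher and 8 lower, the same adjusted over the list alone (camera adjusted p = 0.210 in limma), with a median between -0.27 and 0.02 over the settings. The scavenger receptor gene Cd163 rose (0.98), whereas Ly6c2 (-1.56), a marker of inflammatory monocytes, Folr2 (-0.76) and Mertk (-0.75) fell. All 5 red blood cell genes tested fell, also when adjusted over the list alone (camera adjusted p = 0.00504 in limma, and adjusted p = 0.316 with an estimated correlation), with Hba-a1 at -1.64, Hba-a2 at -1.62, Hbb-bt at -1.44 and Hbb-bs at -1.36, paralogs whose separate values are uncertain.

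Lists with fewer than 5 genes above the expression limit had no list test in the main setting. The lymphocyte list held 18 genes, most of them below that limit. Cd79a and Cd79b reached a mean of 1 FPKM only through CON (AngII means 0.637 and 0.553 FPKM). All 4 lymphocyte markers tested fell (Igkc -1.59, Cd79a -1.13, Ighm -1.02, Cd79b -0.91), 2 of 4 neutrophil and mast cell markers fell (Mcpt4 -2.22, or -2.88 on nuclear protein-coding genes alone, and Cma1 -1.58), and of 3 adipocyte genes 1 rose (Cidea 0.49) and 2 fell (Cfd -0.88 and Lipe -0.81), with the same numbers adjusted over each list alone. The call of Cd79a was lost without CON replicate 2 or 3 or AngII replicate 1 or 2, with adjusted p from 0.0556 to 0.0677. Of 2 skeletal muscle genes tested, Mylpf fell (-1.17), and its call was lost without CON replicate 1 (adjusted p = 0.0516) or CON replicate 3 (adjusted p = 0.0641). Of 2 sex-linked genes tested, Eif2s3y rose (0.49). The 8 mesothelial and epicardial genes and the 10 lung and thymus genes all lay below a mean of 1 FPKM.

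Most ribosomal protein, immediate early, cell cycle and circadian clock genes were lower, in the libraries with lower endothelial markers (median -1.30). Of 75 cytosolic ribosomal protein genes, 70 fell and none rose (72 and 0 adjusted over the list alone; camera adjusted p = 3.36e-18 in limma, and adjusted p = 0.0832 with an estimated correlation), with a median log2 fold change of -0.76. Rps27 (-1.64), Rps21 (-1.42), Rpl38 (-1.39) and Rps20 (-1.38) fell furthest, and the many processed pseudogenes of this family make single values uncertain. Of 14 immediate early genes, which answer stimuli and tissue handling within minutes, 13 fell and none rose, the same adjusted over the list alone (camera adjusted p = 1.57e-07 in limma, and adjusted p = 0.0832 with an estimated correlation). Egr1 went from 32.4 ± 0.285 to 4.81 ± 0.136 FPKM (-2.63), Klf2 from 100.7 ± 2.13 to 18.7 ± 0.404 FPKM (-2.40), and Ier2 (-2.09) and Fos (-1.84) fell too. Of 30 cell cycle genes in the list, 7 reached a mean of 1 FPKM. All 7 fell, also when adjusted over the list alone (camera adjusted p = 0.00226 in limma, and adjusted p = 0.0832 with an estimated correlation), with Cdc20 at -1.23, Mcm3 at -1.13, Mcm6 at -1.05 and Ccnd1 at -0.95. Cdc20 reached that mean only through CON (1.88 FPKM, against 0.508 FPKM in AngII). The median of the cell cycle list lay between -1.07 and -0.40 over the settings. Of 13 circadian clock genes, 9 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00504 in limma, and adjusted p = 0.0832 with an estimated correlation), including the clock output gene Dbp (-1.27), Ciart (-0.82), Nr1d1 (-0.74) and Nr1d2 (-0.67). Of 19 unfolded protein response genes, 11 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.0362 in limma, and adjusted p = 0.115 with an estimated correlation). Herpud1 (0.81), the chaperone gene Hyou1 (0.67) and Sdf2l1 (0.57) rose and Trib3, a target of the transcription factors ATF4 and CHOP, fell (-1.25). The call of Herpud1 was lost without CON replicate 1 or any AngII library, with adjusted p from 0.0511 to 0.0627. That of Sdf2l1 was lost without AngII replicate 2 (adjusted p = 0.0548) or 3 (adjusted p = 0.0505) and with the replicate block (adjusted p = 0.0503). The list lost its call with a mean of at least 5 FPKM (adjusted p = 0.129), under quantile normalization (0.0615), with GC and length trends removed (0.0620) and on nuclear protein-coding genes alone (0.0621).

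Among the 12 largest rises by the rule, after Acta1, were Flnc (log2 fold change 3.01), an actin crosslinker of the Z-disc, Bdh1 (2.81), a mitochondrial enzyme of ketone body oxidation, Rcan2 (2.73), Ankrd23 (2.71), Ap4b1 (2.71), Cdh2 (2.69), the cadherin of the intercalated disc, and Lrrc14b (2.74). Bdh1 went from 3.60 ± 0.267 to 28.3 ± 0.960 FPKM and Flnc from 4.95 ± 0.301 to 43.3 ± 1.62 FPKM. Rcan2 was at 3.46 FPKM in CON replicate 2 against 14.3 and 18.2 FPKM in the other CON libraries, and its change was 2.05 without that library. The other 4 were Gm25745 (3.64, and 4.68 without CON replicate 1), Gm2451 (2.87), Gm9108 (2.78) and Gm30970 (2.75), predicted genes whose values are uncertain. Among the 12 largest falls were Cyp1a1 (-3.27; 16.6 ± 1.14 to 1.26 ± 0.0270 FPKM), a target of the aryl hydrocarbon receptor, Isg15, Ifit3, Inmt (-3.07) and the monoacylglycerol lipase gene Mgll (-2.79). Mgll was at 25.2 FPKM in AngII replicate 2 against 6.31 and 5.64 FPKM in the others, and its change was -3.45 without that library. The paralogs Tgtp2 (-2.95), Tgtp1 (-2.82) and Ifit3b (-2.78) are also interferon-induced, with values that near-identical copies make uncertain. The small RNA genes and pseudogene Mir682 (-7.59), Gm27505 (-6.41), Rps6-ps3 (-3.02) and Snord35b (-2.92) made up the rest, and poly(A) selection measures such short transcripts poorly. Over other pseudocounts, rescalings and removal of GC and length trends, Lrrc14b lay between 2.10 and 4.06, Ap4b1 reached 3.48, Mir682 lay between -8.92 and -6.79, Gm27505 between -7.64 and -5.63 and Snord35b between -3.74 and -2.29.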

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

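Removal of GC and length trends, rescaling on nuclear protein-coding genes, the protease list without Usp6nl and an estimated correlation in settings other than the main one were chosen after the results had been seen; the other settings were fixed before the data were examined. Usp25 (log2 fold change 0.43 to 0.76) and Atp2a2 (1.12 to 1.42) stayed past the adjusted p in the same direction under each other scaling, filter, variance model and left-out library, though Usp25, at 1.44-fold, lies under the fold limits. The number of genes called lay between 5338 and 6584 in each setting except the following. It was 3190 with a mean of at least 5 FPKM, where fewer genes (4527) were tested, and 3521 and 1510 with changes of at least 1.5-fold and 2-fold, which are subsets by construction. With an estimated correlation 1 list was called instead of 19. A correlation above the preset 0.01 was not the whole cause, because lists estimated below it weakened too. The unadjusted camera p of cytokine genes (correlation -0.071) went from 0.00317 to 0.0354, and that of cell cycle genes (-0.061) from 0.00103 to 0.0278. For interferon-stimulated genes (-0.026) it went from 9.36e-13 to 0.00139. A call lost with an estimated correlation is thus no sign by itself that the genes of that list move together. The directional test fry, which does not compare a list with other genes, called 26 of the 27, among them lists that camera did not call. The list of mitochondrially encoded genes, not called in any setting, changed the direction of its test with a mean of at least 5 FPKM (median -0.030) and without AngII replicate 1 (medians from -0.042 to -0.011 without any 1 library). The cause was not tested. Equal replicate numbers showed no pairing of the libraries in their deviations from the group means, which correlated at -0.03, 0.05 and -0.01. With 3 libraries in a group, these values cannot exclude a pairing. With the replicate block 5501 genes were called, 5349 of them shared with the 6022. Of the values of named genes under other settings, 3278 stayed on their side of the threshold, 70 lost it, 2 gained it and none changed direction, with Usp36 (14 settings) and Usp38 (9 settings) most affected. Of the list results 5 lost and 9 gained the call, and none of the 9 held with an estimated correlation. That test kept only 1 of the 19 main calls, so it does not set the 9 apart from them. With no filter on low values 24 lists were called and none of the 19 was lost. Those 24 included lists that had too few genes for a test in the main setting, which are not among the 9. Low genes were less precise, with a median coefficient of variation between CON libraries of 13.2% at 1 to 2 FPKM and 2.73% at 100 to 5000 FPKM. Of 1.25-fold changes simulated with 3 libraries per group, 32% were found. That simulation changed 200 genes, far fewer than the 6022 called in the data, so its recovery does not carry over directly.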

Other observations

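The tests of GC and length trends, of a uniform lower share of other cells, of macrophage and endothelial shares and of shared RNA were chosen after the results had been seen, as were the 6 gene lists and the single genes named here, while the tests of left-out libraries and of other splits were not. The p-values of these 6 lists rest on values seen before the choice, so they describe the lists and give no independent support.

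Of 18 genes for the breakdown of branched-chain amino acids, 17 rose and none fell, the same adjusted over the list alone (camera adjusted p = 7.19e-08 in limma over the 6 lists, and adjusted p = 0.0586 with an estimated correlation), with Hibch at a log2 fold change of 1.73 and Mccc1 at 1.46. Of 31 proteasome subunit genes, 23 rose and 2 fell (24 and 3 adjusted over the list alone; camera adjusted p = 8.55e-05 in limma, and adjusted p = 0.0586 with an estimated correlation), with Psmd1 at 0.88 and Psmd12 at 0.82. Of 13 intercalated disc genes, 7 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0348 in limma, and adjusted p = 0.220 with an estimated correlation). The desmosome genes Dsp (1.29) and Pkp2 (0.75) rose with Cdh2, and Ctnnb1 (-0.67) and Tjp1 (-0.55) fell. Endothelial markers (median -1.30) and smooth muscle and pericyte markers (-0.95) were lower in the same libraries.

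Most antigen presentation and cytoskeleton genes tested fell in libraries where endothelial (median -1.30), smooth muscle and pericyte (-0.95) and fibroblast (-0.47) markers were lower too. Interferon-stimulated genes (median -2.01) were lower in them as well. Whether the fall of antigen presentation genes is separate from that of interferon-stimulated genes was not tested. Of 12 MHC class I presentation genes, 9 fell and none rose, the same adjusted over the list alone (camera adjusted p = 4.20e-05 in limma, and adjusted p = 0.0586 with an estimated correlation), with B2m from 798.0 to 358.4 FPKM and Tap1 at -1.51. All 6 MHC class II presentation genes tested fell, also adjusted over the list alone (camera adjusted p = 0.00717 in limma, and adjusted p = 0.0586 with an estimated correlation), with H2-Ab1 at -1.02. Of 19 non-muscle actin and tubulin cytoskeleton genes, 13 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.000314 in limma, and adjusted p = 0.0586 with an estimated correlation). Actb, often used as a reference gene, went from 245.2 ± 4.21 to 69.1 ± 2.95 FPKM (-1.82), and Tmsb10 fell by 1.95 on the log2 scale. The median of each of these 6 lists kept its sign under 4 other scalings and without any 1 library.

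Cardiomyocyte lists rose while endothelial, mural and red blood cell lists fell, calls that were lost with an estimated correlation (adjusted p = 0.0832 for sarcomere and endothelial genes, 0.0959 for smooth muscle and pericyte markers and 0.316 for red blood cell genes). GC content and transcript length were argued against as the whole cause, because after their trends were removed the medians of the sarcomere and endothelial lists still differed by 2.11 on the log2 scale, against 2.24 before. A uniformly lower share of RNA from all other cells was argued against as well, since the macrophage median lay 1.12 above the endothelial one (permutation p = 0.00011 over genes). That p-value treats genes as independent and does not measure spread between mice, and the test was chosen after the medians were seen. A change in the share of some cell types and a change of expression within them stay open, as does an effect of angiotensin II itself, because the labels name no measure of cell numbers.

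All 23 interferon-stimulated genes tested fell, with a median of -2.01. It differed from that of macrophage markers by -1.83 (permutation p = 1e-05 over genes, the smallest that 100000 resamples can give). It differed from that of endothelial markers by -0.71 (permutation p = 0.00046 over genes). These permutations treat genes as independent and were chosen after the medians were seen, so their p-values do not measure spread between mice. A median below that of either marker list argues against a lower share of either cell type as the whole cause. No single library made the pattern, since the median without any 1 library was at most -1.98. A lower interferon response in AngII hearts, or a higher one in the CON mice, may lie behind it, both untested, and a batch that follows the groups cannot be told apart from them.

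More than 50% of the genes passed the threshold, with close replicates. GC and length trends were argued against, because 5939 genes passed after their removal against 6022 before. The spread between libraries of a group exceeded counting noise by a coefficient of variation of 2.07% to 3.44%. It was measured on 98 to 139 well-covered single-transcript genes in each pair of libraries. An excess above 10% was taken as the sign of separate mice, and it was not reached. Libraries from shared or pooled RNA could give the observed size, but the labels say nothing of pooling, so pooled and separate mice cannot be told apart. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many genes, 6022, and the highest other gave 1, but 10 splits are too few for a share under 0.05. No label gives a batch, and a batch that follows the groups cannot be told apart from the treatment.

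Single values chosen after they were seen follow. Nnt, a gene in which C57BL/6J mice are known to carry a deletion, has 2 rows in the table. The row of higher mean read 117.4, 119.9 and 120.2 FPKM in AngII and 36.3, 0.0001 and 36.0 FPKM in CON, and in CON replicate 2 the other row read 17.3 FPKM. The highest values in any library of the atrial genes Myl4, Myl7, Sln and Bmp10 were 1.14, 0.713, 0.108 and 0.0309 FPKM. The pseudogene Gm29216, a near copy of mitochondrial sequence, was at 75787 FPKM in CON and 42299 FPKM in AngII.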
